A study of Mus musculus with 16 samples.

How the data were processed

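Total RNA of mouse plantaris muscle, an ankle plantar flexor of the hindlimb, was sequenced in a design that crossed genotype with surgery. The genotypes were Wild Type (WT) and TRIM28 mKO (KO), the surgeries a sham operation (Sham) and myotenectomy (MTE), which per the labels' protocols was a mechanical overload, and the mice were 9 to 12 weeks old. Per the labels' protocols, cytoplasmic and mitochondrial ribosomal RNA was depleted before library preparation with a stranded kit. Whether the counting used the strand is not given in the sources used here, so a gene and its antisense partner may share reads in the counts.

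The authors deposited a table of estimated counts (expected counts, not all whole numbers) per Ensembl gene. Its unit was taken from the file header, which calls the values raw reads, and from the values, of which 90.9% lay within 0.01 of a whole number. Per the submitters' processing notes, the tools were STAR, RSEM and edgeR and the genome build was GRCm38; versions and roles are not given in the sources used here. The authors' count table held 17230 genes, and genes with few reads had already been removed from it by a filter that is not stated. The authors also deposited log2 values per group and per library, which per the file headers are TMM-normalised and relative to the mean of the WT Sham libraries. These log2 values differed from those computed here from the counts by a median of 0.00013. Per the file headers, the authors' p-value columns hold the p-values of a 2-way analysis of variance and the FDR-adjusted p-values of pairs of groups. The tool behind each p-value column of the authors is not stated. The authors' table of comparisons held 17217 genes, and the other 13 genes of the count table were used from the counts alone.

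The labels describe 16 samples, 4 per group. The tables used here held 15 libraries, 4 each for WT Sham, WT MTE and KO MTE and 3 for KO Sham. The tests had been planned for 16 samples and were run on the 15. The KO Sham columns are headed as samples 1 to 3, but with 3 columns for 4 labelled samples the numbers may have been reassigned. They were therefore not matched to labelled samples or to other libraries by number and are called columns 1 to 3, and the libraries of the other 3 groups are called the numbered libraries. Total counts ran from 21.1 M to 69.2 M per library. Libraries of one group were compared before averaging: chi-square per gene was at least 43.3 for every pair, so no 2 were copies of one another, and each counted as 1 replicate.

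Estimated counts were rounded to whole numbers, genes were filtered with filterByExpr by group, libraries were scaled by TMM, and 4 group means were fitted to all 15 libraries with edgeR's quasi-likelihood model (edgeR 4.0.16, robust, R 4.3.3). Of the genes, 17212 passed the filter and were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene below comes from this edgeR fit unless another tool is named. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. CPM are counts scaled to library size after TMM, and M stands for mega, given as mean ± SD. The 4 comparisons were WT MTE against WT Sham, KO Sham against WT Sham, KO MTE against WT MTE and KO MTE against KO Sham. The interaction is the overload response of KO minus that of WT. Trim28 was also tested with an exact two-sided permutation test of log2 CPM. Gene positions are from GENCODE M21, which uses the same build GRCm38, and 20 genes had no symbol there.

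Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with adjustment over 36 lists per comparison. Each list was also tested with a correlation estimated from the data and with fry, which tests whether a list's genes move, on balance, one way. The lists, the tests, the rule for naming genes and the alternatives other than those marked as chosen later were fixed before the data were examined. The lists were the TRIM28 silencing complex, imprinted genes, numbered Zfp zinc finger genes, germline genes, interferon-stimulated genes, ribosome biogenesis, cytosolic ribosomal proteins, extracellular matrix, macrophage markers and other leukocyte markers. Further lists were satellite cell and myogenic regulators, developmental sarcomere genes, mechanical stress response, neuromuscular junction and denervation, atrogenes, proteasome subunits, autophagy and lysosome, and oxidative phosphorylation subunits. Others were fatty acid oxidation and citrate cycle, glycolysis and glycogen, slow fibre genes, fast fibre genes, cell cycle, amino acid and ATF4 response, p53 targets, growth factor signalling, and heat shock and unfolded protein response. The rest were markers of endothelial, fibro-adipogenic progenitor, smooth muscle and pericyte, Schwann, tendon and adipocyte cells, erythroid genes, immediate early genes and mitochondrially encoded genes. Several members sit on more than 1 list, such as Myog and Lmod2.

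Named genes were, per comparison, Trim28, the 10 called genes with the largest increase and the 10 with the largest decrease among those with a mean log2 CPM of at least 1, no overlap between the groups and an established symbol, and for each list up to 4 members with the smallest adjusted p, plus members named in another comparison. No gene met the rule for the interaction. Estimated counts that are not whole show reads split between similar genes, and genes whose counts were whole in few libraries are called uncertain where named.

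The fit was tested on simulated data made from the WT Sham means and the library sizes of these samples. No simulated library was made to stand apart from its group, so the false calls below do not cover such libraries. For WT MTE against WT Sham, 58 of 80 genes changed 4-fold, 16 of 60 changed 2-fold and 6 of 60 changed 1.5-fold were recovered among 16783 genes, with 1 false call. For KO Sham against WT Sham the recovered genes were 56, 12 and 2 among 16819, with 4 false calls. For KO MTE against WT MTE they were 68, 28 and 4 among 16816, with 3 false calls, and for KO MTE against KO Sham 57, 16 and 1 among 16802, with 3 false calls. A simulated list raised 1.5-fold was called in each of the 4 comparisons with no other list called, in data that held no correlation between genes.

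Alternatives were RLE size factors, DESeq2 1.42.0, limma voom, no filter on low counts, a filter of at least 1 CPM in at least 8 libraries, fits of the compared groups alone, a replicate block, a fold of at least 2, and leaving out each library in turn. Chosen after seeing the data were voom with sample quality weights, 1 surrogate variable (sva 3.50.0) and leaving out the 2 libraries that stood apart, WT Sham 1 and KO Sham column 3. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in python 3.11.15.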

Results

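RNA of mouse plantaris muscle was sequenced to ask how TRIM28 acts in muscle at rest and under overload. TRIM28 is a corepressor that zinc finger proteins of the KRAB class recruit to DNA, where it silences retroelements and some genes. The tables held 15 libraries in 4 groups: WT Sham (n = 4), KO Sham (n = 3), WT MTE (n = 4) and KO MTE (n = 4). Total counts per library averaged 35.7 M ± 6.09 in WT Sham, 35.4 M ± 12.9 in KO Sham, 36.1 M ± 6.44 in WT MTE and 48.9 M ± 14 in KO MTE (SD). The lowest total was 21.1 M in KO Sham column 3 and the highest 69.2 M in KO MTE 2. Within a group, pairs of libraries correlated at 0.932 to 0.986 across genes. The labels do not say whether libraries of a group came from separate mice, so p-values measure the spread between these samples.

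Each of 2 libraries stood apart from its group. WT Sham 1 held more macrophage and interferon-stimulated transcripts than the other WT Sham libraries, with a mean of 6.0 log2 CPM over the macrophage markers against 2.93 to 3.40, and 3.91 over the interferon-stimulated genes against 1.85 to 1.93. Its share of counts from mitochondrially encoded genes was 6.95% against 13.3% to 14.4%. KO Sham column 3 had the highest mitochondrial share of all libraries, 20.5%, and the lowest mean over the extracellular matrix list, 4.43 log2 CPM against 5.98 and 6.03 in the other KO Sham columns. The mean mitochondrial share was 12.2% ± 3.53 in WT Sham, 14.7% ± 5.08 in KO Sham, 7.80% ± 1.31 in WT MTE and 8.33% ± 0.867 in KO MTE (SD).

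The targeted gene was examined first in every library. Trim28 (ENSMUSG00000005566, chromosome 7, 12999114 to 13031035, GRCm38) lay at 27.8 to 49.0 CPM in the 4 WT Sham libraries and at 12.7, 11.6 and 5.39 CPM in KO Sham columns 1, 2 and 3. It lay at 60.9, 51.9, 47.3 and 35.3 CPM in WT MTE 1 to 4 and at 30.3, 25.2, 18.0 and 24.8 CPM in KO MTE 1 to 4. Every KO library was therefore below every library of the WT group with the same surgery. Which part of the gene the deletion removes, and in which cells, is not given in the sources used here. In Sham muscle Trim28 was 3.58-fold lower in KO, 9.91 ± 3.95 against 35.8 ± 9.49 CPM (log2 fold change -1.84, SE 0.30, adjusted p = 0.0101), and the exact permutation p of 0.0286 was the smallest that 35 arrangements allow. When only the Sham groups were fitted the adjusted p was 0.183. In MTE muscle it was 24.6 ± 5.08 CPM in KO and 48.9 ± 10.6 CPM in WT (log2 fold change -0.99, SE 0.26), with an adjusted p of 0.0822 that missed the threshold and an exact permutation p of 0.0286, the smallest possible with 70 arrangements. Other fits put the MTE difference past the threshold, with an adjusted p of 0.0117 by DESeq2, 0.0455 by limma voom, 0.0248 when only the MTE groups were fitted and 0.0138 with a replicate block on the numbered libraries. So did 3 alternatives chosen after seeing the data, sample quality weights (0.00238), 1 surrogate variable (0.000561) and leaving out WT Sham 1 and KO Sham column 3 (0.00648). The MTE difference stayed uncalled with RLE size factors, with no filter and with the filter of at least 1 CPM in at least 8 libraries. It also missed the threshold in edgeR whenever a single MTE library was left out, with an adjusted p of 0.0752 to 0.220. Within KO muscle Trim28 rose 2.46-fold with overload (log2 fold change 1.30, SE 0.29, adjusted p = 0.00684, exact permutation p = 0.0286). Without KO Sham column 3 this log2 fold change was 1.01 (adjusted p = 0.0259). Within WT the log2 fold change of Trim28 was 0.45 (SE 0.26, adjusted p = 0.224, exact permutation p = 0.143). A difference between the KO and WT responses was not called, since edgeR called 0 genes for the interaction. Trim28 passed the threshold in WT overload with a replicate block on the numbered libraries (adjusted p = 0.0493) and, in alternatives chosen after seeing the data, with sample quality weights (0.00740) and without WT Sham 1 and KO Sham column 3 (0.0201).

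**Figure D1:**
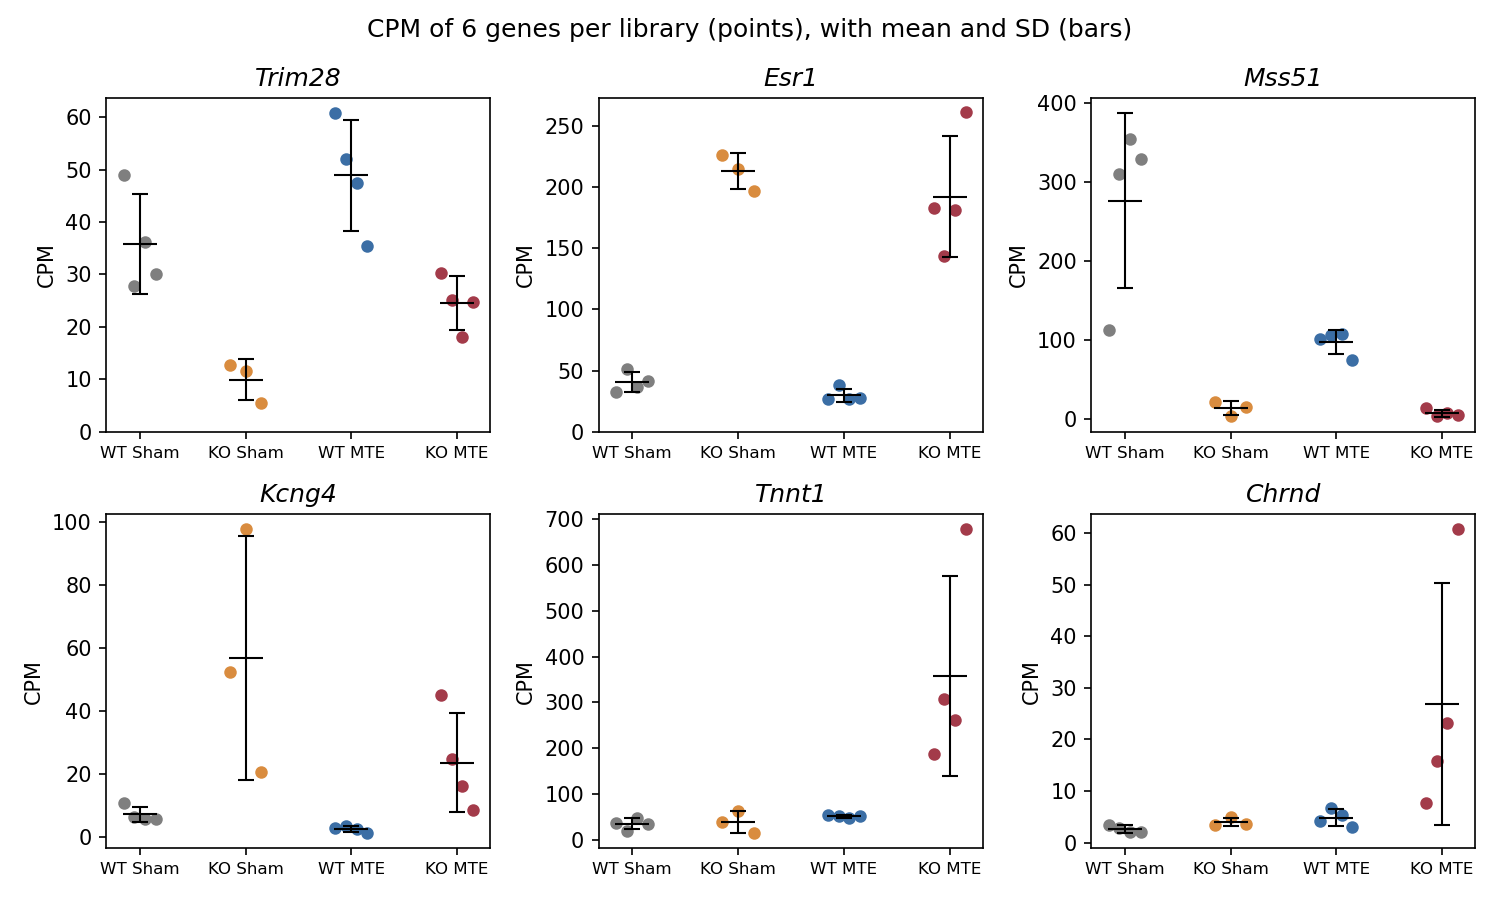
Expression in CPM of Trim28, Esr1, Mss51, Kcng4, Tnnt1 and Chrnd in each of the 15 libraries by group, with group means and SD. Trim28 lies at 5.39 to 12.7 CPM in KO Sham and 27.8 to 49.0 CPM in WT Sham, and Esr1 lies at 144 CPM or more in every KO library and at 51.2 CPM or less in every WT library.

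The first comparison asked what mechanical overload changed in WT muscle (WT MTE against WT Sham, n = 4 each). Of the lists, the extracellular matrix had the highest median log2 fold change, camera called cell cycle, developmental sarcomere and mechanical stress lists higher as well, and it called lists of oxidative and glycolytic metabolism and of fast fibres lower. None of these lists was called with an estimated correlation (lowest adjusted p = 0.315). Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), which encodes the matricellular protein periostin, rose 41.2-fold. It went from 120 ± 58.6 to 4933 ± 1925 CPM (log2 fold change 5.37, SE 0.45, adjusted p = 5.33e-06). Lrrc15, a membrane protein of activated fibroblasts, rose 59.2-fold, from 1.52 ± 1.40 to 89.9 ± 48.1 CPM (log2 fold change 5.89, SE 0.62, adjusted p = 2.71e-05). Klhl33 (chromosome 14, 50888582 to 50897507), a kelch-like gene, fell 7.72-fold, from 138 ± 51.7 to 17.9 ± 4.85 CPM (log2 fold change -2.95, SE 0.35, adjusted p = 6.38e-05).

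In all, 2435 genes were higher and 1920 lower after overload in WT, of 17212 tested, and 1485 and 579 of these changed at least 2-fold. The other genes with the largest increases were C1qtnf3, a secreted C1q/TNF-related protein (log2 fold change 5.82), Tnn, which encodes tenascin-N (5.65), Cthrc1, a secreted collagen triple helix repeat protein (5.49), Mest, an imprinted gene (4.75), Adam12, a disintegrin metalloprotease (4.72), Mmp12, the macrophage elastase (4.36), Ddah1, which degrades dimethylarginine (4.20), and Ltbp2, a latent TGF-beta binding protein (4.16). Among the largest decreases were Chac1, which degrades glutathione (-2.96), Inmt, an N-methyltransferase (-2.86), Pfkfb3, which makes an activator of phosphofructokinase (-2.83), Ces1d, a carboxylesterase (-2.43), Fer1l6 (-2.42) and Lrrc38 (-2.40). Myhas, an antisense transcript of the myosin heavy chain locus, had a log2 fold change of -2.59, which is uncertain because the strand setting is not given. BC023105, a processed pseudogene (-4.19), and Gbp10, a guanylate-binding protein gene whose reads are shared with similar genes (-4.09), were also called. WT Sham 1 held 658 CPM of BC023105 against 16.02 to 21.3 in the other WT Sham libraries, and 521 CPM of Gbp10 against 14.4 to 46.8. The call of BC023105 was lost with limma voom (adjusted p = 0.101) and when only these groups were fitted (0.0598). Without WT Sham 1 the counts were 3674 higher and 3021 lower, and without WT Sham 2 1246 genes were lower.

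Of 35 extracellular matrix genes, 34 rose and 0 fell (34 adjusted over the list alone), with a median log2 fold change of 2.65. Besides Postn, the smallest adjusted p belonged to Col5a2, a fibrillar collagen chain (3.57), Fstl1, a follistatin-like secreted protein (2.99), and Fbn1, fibrillin (2.47). Camera gave this list an adjusted p of 5.09e-22, against adjusted p = 0.315 with an estimated correlation. Of 26 cell cycle genes, 19 rose (23 adjusted over the list alone; median 1.83; camera adjusted p = 6.24e-09), among them Kif20a, a mitotic kinesin (2.53), Rrm2, a ribonucleotide reductase subunit (1.82), and Cdk1 (2.68). Of 10 developmental sarcomere genes, 8 rose (8 adjusted over the list alone; median 1.95; camera adjusted p = 0.000246), led by Myl6b, a myosin light chain (3.50), and Tnnt2, cardiac troponin T (2.69). Myh8 (3.50) and Myh3 (2.08), the perinatal and embryonic myosins, share reads with other myosin genes and are uncertain. Of 14 mechanical stress genes, 10 rose (10 adjusted over the list alone; median 1.49; camera adjusted p = 0.000325), including Csrp3, a muscle LIM protein of the Z-disc (2.64), and Ankrd1, an ankyrin repeat protein (3.10). Each of these 3 lists had adjusted p = 0.418 with an estimated correlation.

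Among imprinted genes, 15 of 30 rose and 3 fell (15 and 3 adjusted over the list alone; median 0.58; camera adjusted p = 0.00130), and adjusted p = 0.370 with an estimated correlation. Besides Mest, those leading were Plagl1, a zinc finger gene (2.92), Igf2, the fetal growth factor (2.03), and Grb10, an adaptor of the insulin receptor (1.40). Heat shock and unfolded protein response genes had 11 of 18 higher and 1 lower (11 and 1 adjusted over the list alone; median 0.72; camera adjusted p = 0.000382), led by Manf (1.12) and the protein disulfide isomerase Pdia4 (1.30). Markers of fibro-adipogenic progenitors had 8 of 13 higher (8 adjusted over the list alone; median 0.75; camera adjusted p = 0.000527), led by Mfap5 (2.66) and Dpt (1.5). Of the immediate early genes, 8 of 15 rose (9 adjusted over the list alone; median 1.19; camera adjusted p = 0.00587), led by Ier3 (1.33) and Egr3 (2.0). The last 3 lists each had adjusted p = 0.418 with an estimated correlation. Of 26 growth factor genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.24; camera adjusted p = 0.0425), with adjusted p = 0.315 with an estimated correlation. Igf1, insulin-like growth factor (2.61), and Il6, a cytokine (2.88), rose. The camera call of this list was lost without WT Sham 1 (adjusted p = 0.138) and without WT MTE 1 (0.0874). Cytosolic ribosomal proteins had 3 of 72 higher (0 adjusted over the list alone; median 0.30; camera adjusted p = 0.00438), with adjusted p = 0.688 with an estimated correlation, and all 3, Rpl3, Rps12 and Rpl12, share reads with pseudogenes and are uncertain. Macrophage markers had 3 of 22 higher (2 adjusted over the list alone; median 0.81; camera adjusted p = 0.000147), with adjusted p = 0.536 with an estimated correlation. They were Trem2, a lipid receptor of macrophages (3.02), Mrc1, the mannose receptor (1.53), and Gpnmb (1.27). WT Sham 1 raised the control level of these markers, and their median was 2.17 without it. The median of fibro-adipogenic progenitor markers was then 1.27.

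Of 79 oxidative phosphorylation subunits, 47 fell and 0 rose (51 lower and 1 higher adjusted over the list alone), with a median of -0.51. Sdha, the flavoprotein of complex II, had -0.91 and Ndufa9 -0.68. Of 35 genes of fatty acid oxidation and the citrate cycle, 20 fell (25 adjusted over the list alone; median -0.63), led by Suclg1, a succinate-CoA ligase subunit (-0.89). Of 23 genes of glycolysis and glycogen, 11 fell and 1, Pgm2, rose (12 and 1 adjusted over the list alone; median -0.72), led by Phkg1, a phosphorylase kinase subunit (-1.65). Of 14 fast fibre genes, 8 fell (10 adjusted over the list alone; median -0.70), led by Myoz1 (-1.21) and, with shared reads, Myh4 (-1.73), followed by the calcium buffer Pvalb (-1.62). The camera adjusted p of these 4 lists were 6.30e-15, 2.96e-10, 7.89e-08 and 3.51e-06, and with an estimated correlation adjusted p = 0.315 for each. Camera also called mitochondrially encoded genes lower (5 of 15 lower, 10 adjusted over the list alone; median -0.89; adjusted p = 0.000147, and adjusted p = 0.500 with an estimated correlation). The mitochondrial share given for the groups counts the same genes, so it is not separate evidence. Members with the smallest adjusted p included the mitochondrial ribosomal RNA genes mt-Rnr2 and mt-Rnr1, whose RNA was a target of the depletion. Atrogenes, genes of muscle protein breakdown, had 5 of 21 lower and 1 higher (5 and 1 adjusted over the list alone; median -0.32; adjusted p = 0.0322), adipocyte markers 0 of 9 called (0 adjusted over the list alone; median -0.99; adjusted p = 0.00666), both with adjusted p = 0.418 with an estimated correlation. The atrogene members leading were Foxo4 (-1.16), Mstn, the inhibitor of muscle growth myostatin (-1.68), and Fbxo32, the ubiquitin ligase atrogin (-2.15). The camera call of atrogenes was lost without WT Sham 1 (adjusted p = 0.0807) and without WT MTE 2 (0.0932). Numbered Zfp genes had 19 of 362 higher and 59 lower (14 and 51 adjusted over the list alone; median -0.18, and -0.30 without WT Sham 1; adjusted p = 0.000546), with adjusted p = 0.553 with an estimated correlation.

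The remaining lists were not called by camera in WT overload. Calls were 5 of 17 satellite cell and myogenic regulators higher, among them Myog, the myogenic factor myogenin (2.04), 5 of 20 neuromuscular junction and denervation genes higher, among them Runx1 (2.30). There were 8 of 22 amino acid and ATF4 response genes higher with 2 lower, among them Aldh18a1, an enzyme of proline synthesis (2.31). P53 targets had 4 of 17 higher and 2 lower, and autophagy and lysosome genes 5 of 30 higher and 5 lower. There were 3 of 10 smooth muscle and pericyte markers higher and 2 lower, 3 of 9 tendon markers higher, among them the tendon transcription factor Scx (1.77), and 3 of 16 genes of the TRIM28 silencing complex higher with 1 lower. Slow fibre genes had 2 of 12 higher and 1 lower, and endothelial and Schwann cell markers each had 1 higher and 1 lower. In ribosome biogenesis Myc rose (1 of 32), in other leukocyte markers Flt3 (1 of 12), and in proteasome subunits Psmd5 (1 of 37). Adjusted over the list alone, the counts were 5 higher for the myogenic and for the junction list, 10 and 2 for amino acid response, 4 and 3 for p53 targets, 6 and 5 for autophagy, 5 and 3 for smooth muscle, 3 and 1 for tendon, and 3 and 1 for the silencing complex. They were 2 and 1 for slow fibre, 1 and 1 for endothelial, 1 and 0 for Schwann cells, 1 for ribosome biogenesis, 1 for other leukocytes and 0 for the proteasome. EdgeR called 0 of 4 germline genes (median -0.40), 0 of 30 interferon-stimulated genes (0.24, and 0.97 without WT Sham 1, with camera adjusted p = 2.15e-05) and 0 of 6 erythroid genes (-1.48, and -0.47 without WT Sham 1), and 0 of each adjusted over the list alone. In 2 lists the signs differed: proteasome subunits had a median of 0.029 and a mean of -0.021, and other leukocyte markers a median of 0.097 and a mean of -0.0087, with camera pointing up for both. Over all 36 lists, camera called 11 up and 8 down, 0 with an estimated correlation, and fry 19.

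The second comparison asked what loss of TRIM28 changed in muscle without overload (KO Sham, n = 3, against WT Sham, n = 4). EdgeR called 88 genes, and 3 of the 35 splits of these 7 libraries, the real one included, called at least as many. Zfp873 and 7 genes near it on chromosome 10, the imprinted long noncoding RNA Rian and the estrogen receptor gene Esr1 were higher, and Mss51, Mettl21c and Flrt1 were lower. Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614) was 5.27-fold higher, 213 ± 14.8 against 40.4 ± 8.17 CPM (log2 fold change 2.40, SE 0.20, adjusted p = 5.92e-05). Mss51 (ENSMUSG00000021815, chromosome 14, 20482867 to 20496901), a zinc finger protein of skeletal muscle, was 20.9-fold lower, 13.2 ± 9.07 against 276 ± 111 CPM (log2 fold change -4.39, SE 0.64, adjusted p = 0.00473). Mettl21c, a protein lysine methyltransferase, was 12.5-fold lower, 4.18 ± 2.27 against 51.6 ± 22.8 CPM (log2 fold change -3.64, SE 0.46, adjusted p = 0.00225).

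There were 57 genes higher and 31 lower in KO Sham. The largest increases were in Kcng4, a modifier subunit of potassium channels (log2 fold change 2.99), Rian (2.45), Esr1, AU041133 (2.40), Fam174b (2.19), BC024063 (2.13), Zfp873 (1.92), Zfp781 (1.90), Zfp934 (1.90) and Mfsd4a, a transporter-like gene (1.89). BC024063, Zfp781 and Zfp934 share reads with similar genes and are uncertain. The other large decreases were in Flrt1, a leucine-rich repeat transmembrane protein (-3.16), Chac1 (-2.34), Mrln, a micropeptide that inhibits the calcium pump of the sarcoplasmic reticulum (-2.33), Asb15 (-2.09), Nhs (-2.05), Trim28, the LIM protein gene Fhl1 (-1.52) and the kinase gene Pak1 (-1.5). When only the Sham groups were fitted, 4 genes were higher and 2 lower, and of these 20 genes Esr1 and Flrt1 alone stayed called. Leaving out KO Sham column 1 gave 31 higher and 9 lower, column 2 27 and 12, WT Sham 3 27 and 18, WT Sham 4 30 and 20, WT Sham 2 36 and 20, and leaving out WT Sham 1 gave 52 lower. Of these 20 genes, 12 stayed called in every omission, and Kcng4, Zfp781, Flrt1, Chac1, Mrln, Asb15, Fhl1 and Pak1 did not.

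On chromosome 10, 9 of the 24 tested genes from Gna15 (start 81502306) to Gm4924 (end 82422882) were higher in at least 1 of the 2 genotype comparisons, a window chosen after the values were seen. Among them, Zfp873 (82048123 to 82064745) lay at 7.28 ± 0.369 CPM in KO Sham and 1.92 ± 0.460 CPM in WT Sham, and AU041133 (82128013 to 82153065) at 9.77 ± 2.25 and 1.84 ± 0.451 CPM. Of the numbered Zfp genes, 7 of 362 were higher and 0 lower (15 and 0 adjusted over the list alone; median 0.16; camera adjusted p = 3.70e-07), and adjusted p = 0.744 with an estimated correlation. The median was 0.087 without WT Sham 1 and 0.032 without KO Sham column 3. Camera also called heat shock and unfolded protein response genes up (0 of 18 called, 3 adjusted over the list alone; median 0.31; adjusted p = 0.000292) and fatty acid oxidation and citrate cycle genes up (0 of 35 called, 0 adjusted over the list alone; median 0.16; adjusted p = 0.0125), each with adjusted p = 0.744 with an estimated correlation. Hspa5, an endoplasmic reticulum chaperone, had a log2 fold change of 0.61 (adjusted p = 0.231).

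**Figure D2:**
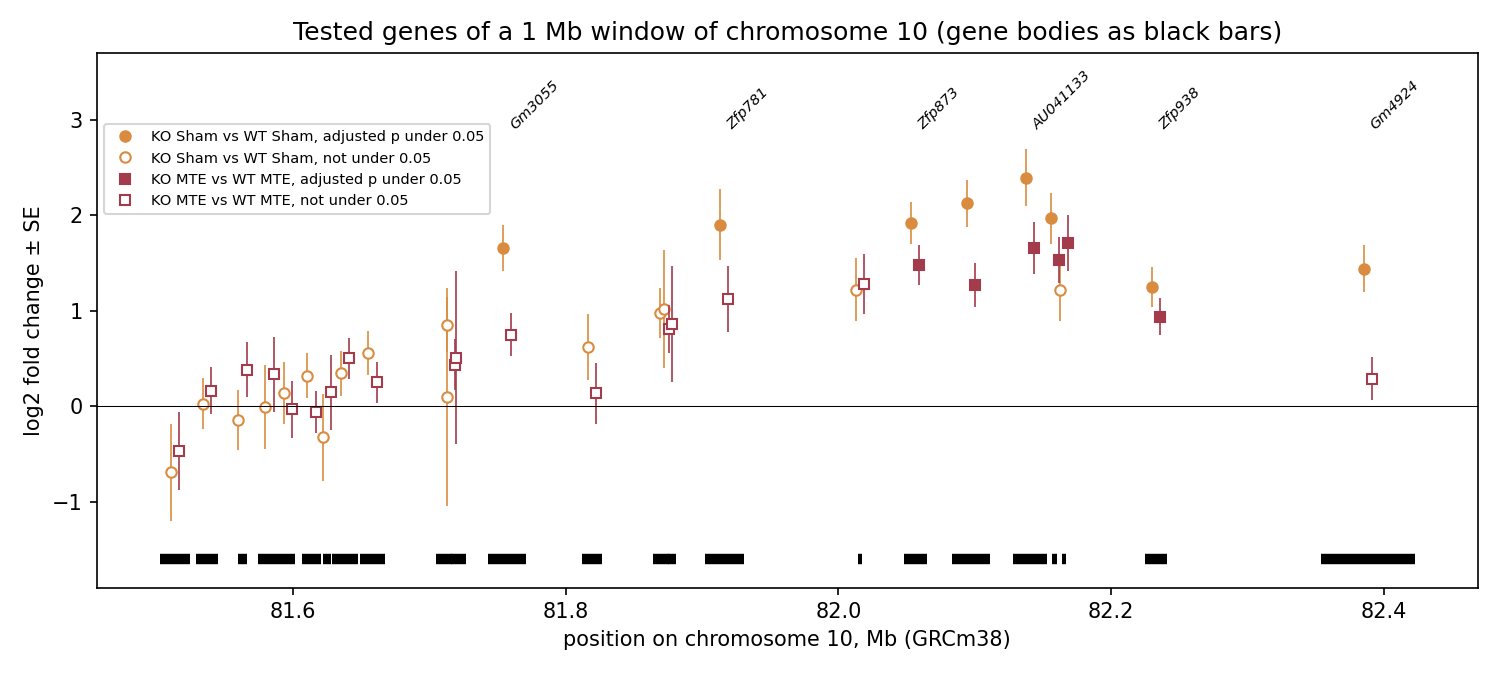
Log2 fold changes of KO against WT in Sham and in MTE muscle for the 24 tested genes along chromosome 10 from Gna15 (start 81502306) to Gm4924 (end 82422882, GRCm38), at each gene's position. Zfp873 has 1.92 in Sham and 1.48 in MTE, and AU041133 2.40 and 1.66.

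Camera called 10 lists lower in KO Sham, and in these 2 libraries stood apart. Macrophage markers had a median log2 fold change of -2.11 with 0 of 22 called (16 lower adjusted over the list alone; camera adjusted p = 1.97e-06), and adjusted p = 0.744 with an estimated correlation. The median was -0.25 without WT Sham 1 and 0.041 without both libraries that stood apart. Lyz2, lysozyme of myeloid cells, had -2.53 (adjusted p = 0.296). Other leukocyte markers had a median of -0.85 and interferon-stimulated genes -0.58, which was 0.18 without WT Sham 1. The extracellular matrix list had -0.17, and 0.15 without KO Sham column 3, the library with the lowest matrix level. The remaining medians were -0.18 for cytosolic ribosomal proteins, -0.20 for fast fibre genes, -0.18 for glycolysis and glycogen, -0.29 for endothelial, -0.34 for fibro-adipogenic progenitor and -0.39 for adipocyte markers. Without KO Sham column 3 they were, in this order, -0.068, -0.033, 0.0013, -0.16, -0.18 and -0.060. EdgeR called 0 members of these 10 lists over all genes. Adjusted over the list alone it called 3 fast fibre genes and 2 of glycolysis lower and 0 of the other 7 lists. Their camera adjusted p, in the order of leukocyte, interferon, matrix, ribosomal, fast fibre, glycolysis, endothelial, progenitor and adipocyte lists, were 0.00321, 0.0101, 0.0303, 0.000292, 0.00114, 0.0167, 0.0217, 0.00554 and 0.0125, with adjusted p = 0.744 with an estimated correlation for each. Outside the called lists, Casq2, the slow and cardiac calsequestrin, was higher (1.10), and Rian was 1 of 30 imprinted genes called (3 higher and 1 lower adjusted over the list alone; median 0.060). Median, mean and test differed in sign for the TRIM28 silencing complex (0.14, mean -0.021, up), proteasome subunits (0.029, -0.15, up) and p53 targets (0.060, -0.23, down), while the test pointed up against negative medians and means for myogenic regulators and mechanical stress genes, and down against positive ones for tendon markers. Fry called 0 lists. Without KO Sham column 3, of the 13 lists called by camera only the macrophage, other leukocyte and heat shock lists kept their calls, and the other 10 had adjusted p of 0.0691 to 0.374. Without WT Sham 1 the calls of interferon (adjusted p = 0.483), matrix (0.15) and fatty acid oxidation genes (0.483) were lost. Calls were also lost for glycolysis without WT Sham 2 (0.0576), for matrix and adipocyte genes without WT Sham 4 (0.197 and 0.0660), for endothelial and adipocyte genes without KO Sham column 1 (0.0752 and 0.169) and for interferon without KO Sham column 2 (0.131).

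The third comparison asked what loss of TRIM28 changed in overloaded muscle (KO MTE against WT MTE, n = 4 each). Esr1, Kcng4, the troponin genes Tnnt1 and Tnnc1 and the acetylcholine receptor genes Chrnd, Chrna1 and Chrng were higher in KO, while Mss51, the secreted peptide gene Ostn and Mustn1 were lower. Kcng4 (chromosome 8, 119623854 to 119635680) was 9.22-fold higher, 23.6 ± 15.7 against 2.53 ± 0.914 CPM (log2 fold change 3.21, SE 0.54, adjusted p = 0.00818). Esr1 was 6.43-fold higher, 192 ± 49.3 against 29.9 ± 5.35 CPM (log2 fold change 2.68, SE 0.20, adjusted p = 1.02e-05). Mss51 was 14-fold lower, 6.93 ± 4.33 against 97.1 ± 15.3 CPM (log2 fold change -3.81, SE 0.55, adjusted p = 0.00375).

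In KO MTE, 209 genes were higher and 44 lower, and 120 and 33 of these differed at least 2-fold. Further large increases were in Tnnt1, slow troponin T (log2 fold change 2.80), Chrnd, the acetylcholine receptor delta subunit (2.46), Tspan13, a tetraspanin (2.41), Gsta4, a glutathione transferase (2.38), Tmem53 (2.31), Uchl1, a ubiquitin hydrolase of neurons (2.22), Tnnc1, troponin C of slow and cardiac muscle (2.19), and Rab15 (2.10). Further decreases were in Ostn, which encodes musclin (-2.25), Tspan8 (-2.21), Flrt1 (-2.07), Mustn1, a nuclear protein of the musculoskeletal system (-1.93), Mrln (-1.84), Aldh1a1, a retinaldehyde dehydrogenase (-1.83), Art3 (-1.82), Mettl21c (-1.70) and Asb15 (-1.70). Of the genes that differed in Sham, 33 of the 57 higher were also higher here and 15 of the 31 lower were also lower, against 0.692 and 0.0792 for independent sets, and 0 were called in opposite directions. DESeq2 called 500 higher and 154 lower. Leaving out 1 library gave from 82 higher (without WT MTE 3) to 231 (without KO MTE 1) and from 6 lower (without KO MTE 2) to 38. The higher count was also 117, 101 and 117 without WT MTE 1, 2 and 4 and 86, 135 and 113 without KO MTE 2, 3 and 4, and the lower count was 20, 20, 12 and 18 without WT MTE 1 to 4 and 26 and 11 without KO MTE 3 and 4. Of the 20 genes with the largest differences, 8 stayed called in every omission, and Chrnd, Gsta4, Tmem53, Tnnc1, Ostn, Tspan8, Flrt1, Mustn1, Mrln, Aldh1a1, Mettl21c and Asb15 did not.

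Of 20 neuromuscular junction and denervation genes, 4 were higher (9 adjusted over the list alone), with a median of 0.66: Musk, the kinase that clusters acetylcholine receptors (1.23), Chrnd, Chrna1, the receptor's alpha subunit (2.02), and Chrng, its fetal gamma subunit (3.23). The camera adjusted p was 3.30e-07, and adjusted p = 0.259 with an estimated correlation. The calls of Chrng and Chrnd were lost with limma voom (adjusted p = 0.113 and 0.0659). Oxidative phosphorylation subunits had 77 of 79 log2 fold changes above 0 with a median of 0.34 and 0 called (0 adjusted over the list alone), a camera adjusted p of 3.00e-18 and adjusted p = 0.259 with an estimated correlation. Ndufa9 had 0.34 (adjusted p = 0.153). Slow fibre genes had 3 of 12 higher, Tnnt1, Tnnc1 and Casq2 (0.99), with 4 adjusted over the list alone, a median of 0.13, a camera adjusted p of 0.00379 and adjusted p = 0.303 with an estimated correlation. Genes of fatty acid oxidation and the citrate cycle (1 of 35 higher, Fh1, fumarase, 0.45; 2 higher and 1 lower adjusted over the list alone; median 0.15; camera adjusted p = 0.0138) and proteasome subunits (0 of 37, 0 adjusted over the list alone; median 0.12; 0.0412) were called up, each with adjusted p = 0.835 with an estimated correlation.

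Lists called lower in KO MTE included growth factor signalling, with 1 of 26 lower (4 adjusted over the list alone; median -0.31; camera adjusted p = 0.00376). Fst, the myostatin inhibitor follistatin, fell by 0.94 on the log2 scale (SE 0.20, adjusted p = 0.0331). This was the 1 list that fry called (adjusted p = 0.00575), while adjusted p = 0.0916 with an estimated correlation. The extracellular matrix list had a median of -0.48 with 35 of 35 log2 fold changes below 0 and camera adjusted p = 0.00363, macrophage markers -0.50 (0.0412), other leukocyte markers -0.68 (0.00376), cell cycle genes -0.54 (0.00376), adipocyte markers -0.71 (0.0161) and immediate early genes -0.50 (0.00729). EdgeR called 0 genes of these 6 lists, and 0 adjusted over the list alone. With an estimated correlation, adjusted p = 0.835 for matrix and for cell cycle, adjusted p = 0.851 for macrophage, adjusted p = 0.259 for leukocyte, and adjusted p = 0.670 for adipocyte and for immediate early genes. Fbn1 had -0.55 (adjusted p = 0.279) and Tpx2, a spindle factor, -0.73 (adjusted p = 0.236). In uncalled lists, the imprinted genes Peg10 (1.98) and Rian (1.61) were higher (2 of 30; 4 higher and 1 lower adjusted over the list alone; median -0.14, mean 0.087, test up). Also higher were 4 of 362 Zfp genes (4 adjusted over the list alone; median 0.017), Zfp873 (1.48), Zfp938 (0.94), Zfp385c (2.09) and, with shared reads, Zfp934 (1.28). Polr1a, the large subunit of RNA polymerase I, was higher too (0.61). Perp, a p53 target, was lower (-1.27). Median and mean differed in sign for myogenic regulators (0.012, -0.025), fast fibre genes (0.12, -0.023) and heat shock genes (-0.079, 0.018), and for mechanical stress genes both were negative while the test pointed up. Some list calls were lost without single libraries. These were macrophage markers without WT MTE 3 or 4 or KO MTE 1 or 3 (adjusted p = 0.128, 0.0565, 0.0921 and 0.132), adipocyte markers without WT MTE 1 or 3 (0.0565 and 0.109) and immediate early genes without WT MTE 1 (0.107). Fatty acid oxidation lost its call without WT MTE 2 or 4 or KO MTE 1 (0.0693, 0.0781 and 0.246), and the proteasome without WT MTE 2 or KO MTE 2 or 4 (0.635, 0.103 and 0.380).

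The fourth comparison asked what overload changed in KO muscle (KO MTE, n = 4, against KO Sham, n = 3). As in WT, camera called matrix, cell cycle, developmental sarcomere and macrophage lists higher and metabolic lists lower, and here it called the neuromuscular junction list higher as well. None of these lists was called with an estimated correlation (lowest adjusted p = 0.539). Postn rose 23-fold, from 145 ± 72.3 to 3334 ± 867 CPM (log2 fold change 4.53, SE 0.49, adjusted p = 0.000115). Myl6b (chromosome 10, 128494157 to 128498685) rose 25-fold, from 1.37 ± 1.01 to 36.1 ± 6.33 CPM (log2 fold change 4.64, SE 0.54, adjusted p = 0.000146). Klhl33 fell 9.10-fold, from 175 ± 49.4 to 19.2 ± 6.66 CPM (log2 fold change -3.19, SE 0.36, adjusted p = 0.000126).

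There were 2274 genes higher and 2180 lower, of which 1549 and 677 changed at least 2-fold. Other large increases were in C1qtnf3 (log2 fold change 4.74), Mest (4.56), Tnn (4.44), Lrrc15 (4.43), Ccl8, a monocyte chemokine (4.22), Timp1, an inhibitor of metalloproteases (4.15), Cthrc1 (4.11) and Spon2, a matrix protein (4.03). Other large decreases were in Mmp8, the neutrophil collagenase (-3.70), Ces1d (-3.37), Aqp4, a water channel of fast fibres (-2.70), Inmt (-2.64), Adhfe1 (-2.50), Pdk4, a kinase that inhibits pyruvate dehydrogenase (-2.50), Ppl, periplakin (-2.24), and Nnt (-2.38) and Plet1os (-2.27), which are uncertain because of shared reads and an antisense position. The counts depended on KO Sham column 3: without it they were 1278 higher and 953 lower. The call of Pdk4 was then lost (adjusted p = 0.35), and Pdk4 in that column was 1784 CPM. Without KO MTE 2 and KO MTE 4, 1305 and 1381 genes were lower. Of the 20 genes, 16 stayed called in every omission, and Ccl8, Mmp8, Pdk4 and Nnt did not.

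Of the matrix genes, 31 of 35 rose (34 adjusted over the list alone; median 2.26), and the median was 1.95 without KO Sham column 3. The neuromuscular junction list had 10 of 20 higher (10 adjusted over the list alone; median 0.79), among them Runx1 (2.19) and Chrng (6.81). Of 10 developmental sarcomere genes, 8 rose (8 adjusted over the list alone; median 3.14), among them Tnnt2 (3.33) and Tnni1, slow troponin I (3.45). Macrophage markers had 11 of 22 higher (16 adjusted over the list alone; median 1.92), led by Trem2 (3.84), cell cycle genes 14 of 26 (19 adjusted over the list alone; median 1.70), and mechanical stress genes 8 of 14 (8 adjusted over the list alone; median 1.5). Fibro-adipogenic progenitor markers had 8 of 13 higher (9 adjusted over the list alone; median 0.94), imprinted genes 14 of 30 higher and 5 lower (15 and 6 adjusted over the list alone; median 0.94), cytosolic ribosomal proteins 17 of 72 (11 adjusted over the list alone; median 0.51) and interferon-stimulated genes 3 of 30 (1 adjusted over the list alone; median 0.54). The camera adjusted p of these 10 lists ran from 1.27e-19 for matrix to 0.0204 for interferon. With an estimated correlation, adjusted p = 0.539 for 8 of them, adjusted p = 0.552 for ribosomal proteins and adjusted p = 0.697 for interferon.

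Lists called lower in KO overload were fatty acid oxidation and citrate cycle (25 of 35 lower, 29 adjusted over the list alone; median -0.65), oxidative phosphorylation (22 of 79, 23 adjusted over the list alone; -0.22), and glycolysis and glycogen (9 lower and 1 higher of 23, 11 and 1 adjusted over the list alone; -0.39). So were fast fibre genes (5 of 14, 5 adjusted over the list alone; -0.23), adipocyte markers (2 of 9, 7 adjusted over the list alone; -1.29), numbered Zfp genes (112 lower and 15 higher of 362, 121 and 17 adjusted over the list alone; -0.35) and mitochondrially encoded genes (11 of 15, 13 adjusted over the list alone; -1.26, and -0.58 without KO Sham column 3, the library with the highest mitochondrial share). Their camera adjusted p ran from 4.85e-09 to 0.0237. With an estimated correlation, adjusted p = 0.623 for oxidative phosphorylation and adjusted p = 0.539 for each of the other 6. Lpl, lipoprotein lipase (-1.98), Sdha (-0.83) and the hormone gene of adipocytes, Lep (-3.27), were among the members that fell. Median and mean or test differed in sign for the TRIM28 silencing complex (-0.15, mean 0.13), germline genes (0.076, -0.35), other leukocyte markers (0.33, -0.27), growth factor signalling (-0.066, 0.38) and ribosome biogenesis (0.073, 0.082, test down). Fry called 20 lists. Without KO Sham column 2 the camera calls of interferon (adjusted p = 0.128), oxidative phosphorylation (0.145), fast fibre (0.104) and adipocyte genes (0.318) were lost. The interferon call was also lost without KO Sham column 3 (0.106) and without KO MTE 2 (0.0881). Medians moved with single libraries too: without KO Sham column 3 that of fast fibre genes was -0.46, of glycolysis -0.59 and of numbered Zfp genes -0.21, and without KO Sham column 2 that of adipocyte markers was -0.17 and of oxidative phosphorylation -0.12.

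**Figure D3:**
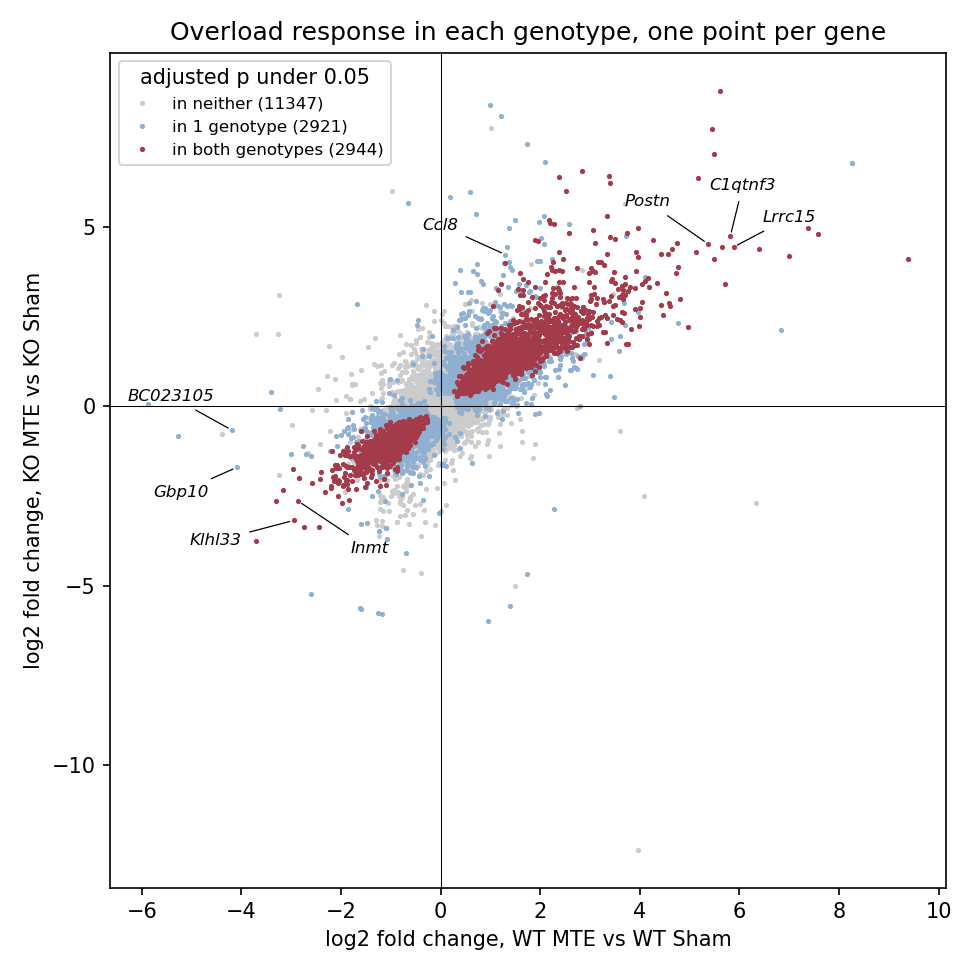
Log2 fold change with overload in KO against that in WT for 17212 genes, coloured by whether the gene was called in both genotypes (2944), in 1 (2921) or in neither (11347). The genes lie along the diagonal (r = 0.776 across genes).

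The interaction asked whether overload changed genes by different amounts in KO and WT. Across genes, the 2 overload responses correlated (r = 0.776, rho = 0.809 over 17212 genes, which are not independent replicates), and they share no library. Of the genes called, 1621 rose in both genotypes and 1323 fell in both, against 322 and 243 for independent sets, and 0 were called in opposite directions. EdgeR called 0 genes for the difference, with 605 at an unadjusted p under 0.05 and a smallest adjusted p of 0.662 for Tspan13. DESeq2 called 10 and limma voom 0. Tnnt1 (log2 difference 2.64, SE 0.62) and Chrng (4.71, SE 1.26), slow fibre and junction genes, had adjusted p of 0.989. As lists, camera called 6 with a higher response in KO: oxidative phosphorylation (median 0.31; adjusted p = 3.08e-13), neuromuscular junction (0.40; 6.52e-05), cytosolic ribosomal proteins (0.20; 0.000181), fast fibre (0.33; 0.000216), glycolysis (0.33; 0.00107) and macrophage markers (1.66; 0.0203). It called 3 with a lower response: heat shock (-0.37; 0.000216), numbered Zfp (-0.16; 0.00237) and growth factor genes (-0.16; 0.0391). With an estimated correlation, adjusted p = 0.565 for oxidative, junction and fast fibre genes, adjusted p = 0.531 for growth factors, adjusted p = 0.790 for heat shock, adjusted p = 0.897 for glycolysis, adjusted p = 0.929 for ribosomal and Zfp genes and adjusted p = 0.993 for macrophage markers, and fry called 0. EdgeR called 0 members of these 9 lists. Adjusted over the list alone it called 1 junction gene higher and 1 heat shock gene lower and 0 in the other 7. The macrophage median was -0.20 without WT Sham 1, and this call was lost without WT Sham 1 (adjusted p = 0.316), KO Sham column 3 (0.537) or WT MTE 1 (0.0827). Without KO Sham column 3 the medians were 0.13 for glycolysis, 0.16 for fast fibre and 0.27 for junction genes. Without both libraries that stood apart the junction median was 0.10 (adjusted p = 0.119) and the ribosomal 0.033 (0.597), and these calls and that of growth factor genes (0.0543) were lost. Camera then called lower responses in KO for the extracellular matrix (median -0.77; 5.15e-09) and cell cycle lists (-0.85; 5.97e-06), which were -0.31 (0.552) and -0.21 (0.535) with all libraries, and matrix also without KO Sham column 3 alone (-0.63; 1.28e-09). The Zfp call was lost without WT Sham 1 (0.434) or KO Sham column 3 (0.895), the ribosomal call without KO Sham column 3 (0.0518) or KO MTE 4 (0.0722). The growth factor call was lost without WT Sham 1 (0.0952), WT Sham 2 (0.0505), KO Sham column 1 (0.0503), KO Sham column 2 (0.246), WT MTE 1 (0.147), KO MTE 2 (0.0828), KO MTE 3 (0.0536) or KO MTE 4 (0.0515). Median, mean and test differed in sign for slow fibre (-0.091, mean 0.29), progenitor (-0.037, 0.071) and smooth muscle genes (-0.0039, 0.10), and the test pointed up against negative medians for tendon and adipocyte markers.

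**Figure D4:**
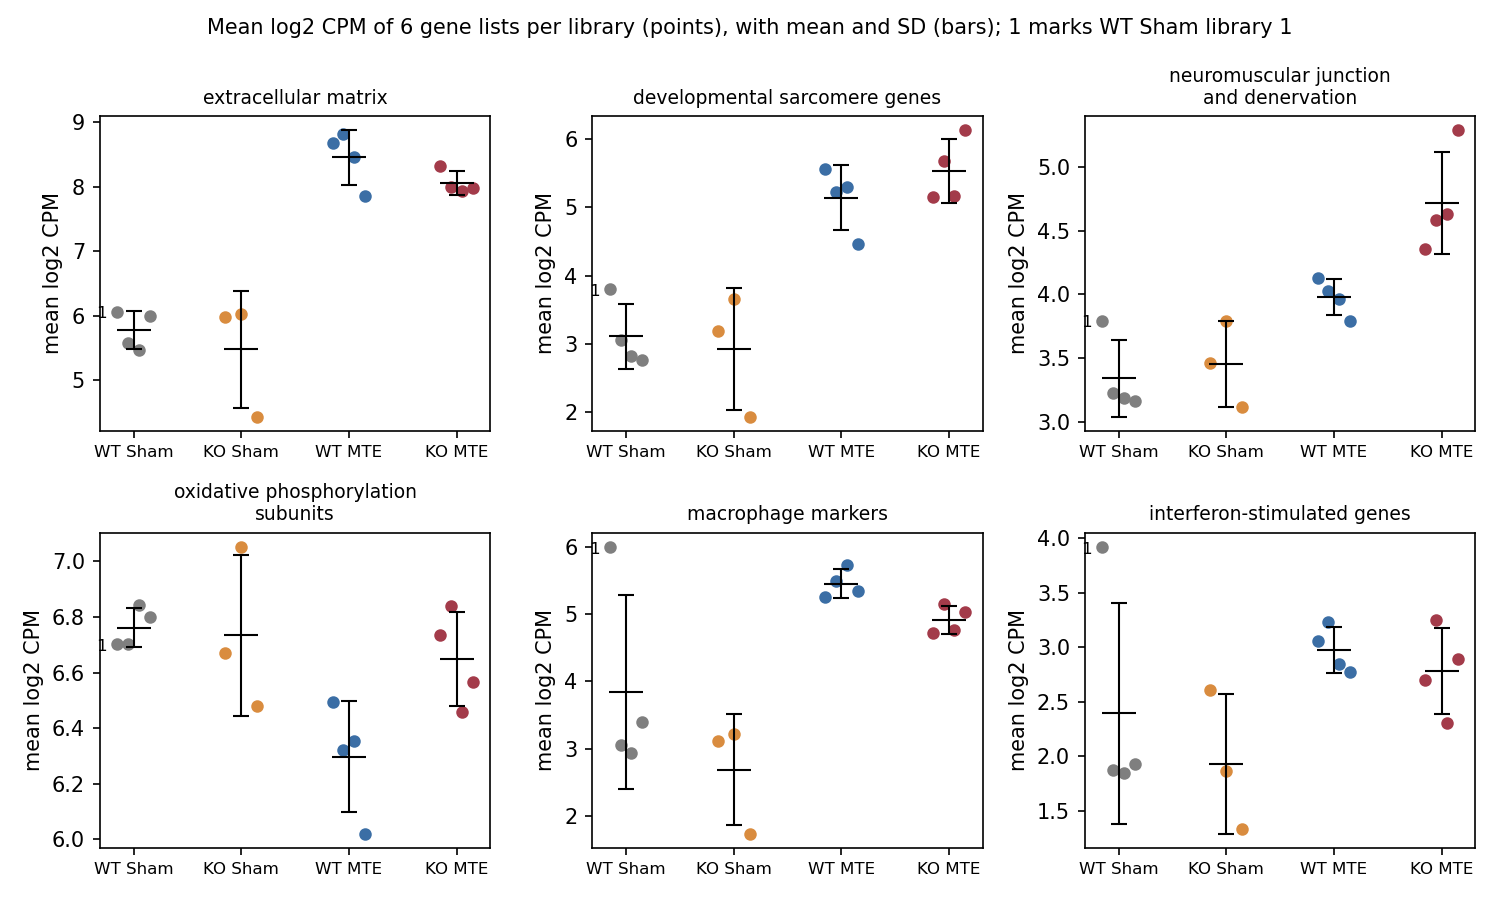
Mean log2 CPM of gene lists in each of the 15 libraries by group. The extracellular matrix list lies at 7.86 to 8.82 in WT MTE and at 5.47 to 6.06 in WT Sham, and the macrophage list lies at 6.0 in WT Sham 1 against 2.93 to 3.40 in the other WT Sham libraries.

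The effect of the knockout in Sham and in MTE muscle, which share no library, correlated at r = 0.399 (rho = 0.422) across the 17212 genes. This r was 0.227 without KO Sham column 2 and 0.466 without KO Sham column 3. The knockout effect in Sham and the overload effect in WT share the WT Sham libraries as controls. Their correlation was 0.024 (rho -0.13), and in 20 simulations of unchanged groups with shared controls it was 0.432 to 0.492. The simulated groups held no overload effect and no correlation between genes. The observed and simulated correlations are therefore on unlike scales, and the simulation does not decide whether the effects are related. The observed covariance was 0.012 against 0.082 simulated, a difference of -0.070. With WT Sham split between the comparisons in 6 ways the correlation ran from -0.41 to 0.10. With shared controls it was 0.234 without WT Sham 1 and 0.351 without both libraries that stood apart, and no simulation was run for these sets. Of the 31 genes lower in KO Sham, 20 were also lower with overload in WT, Chac1 among them, against 3.46 for independent lists, and part of this excess may come from the shared controls. Of the 209 genes higher in KO MTE, 49 fell with overload in WT and 26 rose (23.3 and 29.6 for independent lists), also with shared libraries. Of the 44 genes lower in KO MTE, 14 fell and 13 rose (4.91 and 6.22). Of the 57 genes higher in KO Sham, 7 fell and 9 rose (6.36 and 8.06).

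The authors' deposited table marks 122 genes at an adjusted p under 0.05 for KO Sham against WT Sham, and 70 of the 88 called here are among them. For KO MTE against WT MTE the authors' deposited table marks 1201 genes, which include all 253 called here. The authors' deposited table marks 4940 genes for KO MTE against KO Sham, and 3950 are shared with the calls here. In the authors' deposited table the column headed as WT sham against WT MTE holds the same adjusted p as that for KO MTE against WT MTE in all 17217 genes, so it was not used for WT overload.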

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

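The tests chosen only after the result was seen were the splits for the interaction, the test of shared reads on chromosome 10, the placement of the called genes along the chromosomes, both tests on Esr1 and all tests on WT Sham 1. For normally distributed values, chance puts about 1 in 20 groups past the limit used for a library far from its group. Here 16 of 151 group tests passed it, but most values were CPM, and tests on the same libraries are not independent. KO Sham, with 3 libraries, was not tested in this way.

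In a window of chromosome 10 that holds zinc finger genes among others, 9 of 24 tested genes were called higher in at least 1 genotype comparison, and 5 of them, Zfp873 and AU041133 included, in both. Reads shared between near-identical copies are argued against as the whole cause by 5 members called in Sham. Their counts were whole numbers in at least 14 of 15 libraries. In the MTE libraries their median log2 fold change was 1.4803 (0.288 to 1.66), and 4 of them were called there. Over all 15 tested genes of the window with such counts, called or not, the median was 0.384. The MTE libraries shared the estimate of the spread behind the Sham calls, and the window was chosen from both comparisons. The MTE values are therefore not an independent check. Of 10000 random draws of 233 tested genes, as many as were higher in KO, 0 had 9 within 1 Mb anywhere in the genome. The share was 0.0001 with the real set counted, and the highest draw had 7. This argues against chance placement of 9 separate genes. However, Gm3055, Zfp781 and BC024063 among the 9 had whole counts in 0, 0 and 1 libraries, so shared reads may link their calls. Gm47572 (start 82157101) and Gm47573 (start 82164247), also among the 9, lie close past the end of AU041133 (82153065). Whether they are transcribed separately from AU041133 was not tested. For the members with unshared reads alone the draws do not decide. A linked segment of another strain around a targeted site stays open, because the odds ratio of called genes within 5 Mb of the cluster was 0.34174 (Fisher exact p = 0.376) and its interval of 0.00858 to 1.95 includes 1. Within 5 Mb of Trim28 itself 1 of 60 genes was called, and loss of silencing by TRIM28 may be a further explanation that was not tested.

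Esr1 was higher in both knockout groups, with a lowest KO library of 144 CPM and a highest WT library of 51.2 CPM. A larger share of fibro-adipogenic progenitors, a cell type that can express Esr1, is argued against, because the medians of that marker list were -0.34463 in Sham and -0.30981 in MTE. Reads from a receptor fragment carried by an inducible recombinase stay open: the knockout effect differed between surgeries by 0.28594 on the log2 scale (95% interval -0.32 to 0.89), as a constant source of such reads might give, but gene totals cannot separate a transgene from the gene. Whether the mice carried such a recombinase is not given in the sources used here. A direct effect of TRIM28 loss on Esr1 is a candidate explanation that these data do not test.

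WT Sham 1 carried macrophage and interferon-stimulated transcripts far above the other WT Sham libraries. A WT MTE library under this label is argued against by its extracellular matrix mean of 6.0639 log2 CPM, against 7.86 to 8.82 in WT MTE, a measure chosen after its place on the overload axis (0.62, with WT MTE at 0.89 to 1.07) had left the question undecided. Low depth is argued against by its total of 39.262 M, against 26.6 M to 38.6 M in the other WT Sham libraries. The macrophage difference of KO Sham against WT Sham may rest in part on this library, since its median was -0.2526 without it and -2.11 with it. Camera still called the macrophage list lower without WT Sham 1. KO Sham column 3 had the lowest macrophage mean of the KO Sham columns, 1.73 log2 CPM against 3.11 and 3.22. An injury or infection of the WT Sham 1 sample stays open, and no biological explanation was tested.

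Other values of WT Sham 1 lay far from the other WT Sham libraries. Its mitochondrial share was 6.949%, against 13.3% to 14.4%, and its means were 5.996 log2 CPM for macrophage markers (others 2.93 to 3.40), 3.9145 for interferon-stimulated genes (1.85 to 1.93) and 3.7944 for neuromuscular junction genes (3.16 to 3.22). In CPM, Mmp12 was 3.2179 (0.440 to 0.548), BC023105 658.21 (16.02 to 21.3), Gbp10 520.51 (14.4 to 46.8), Klhl33 61.406 (158 to 173) and Kcng4 10.851 (5.66 to 6.35). In WT Sham 2, Lrrc15 was 3.6097 CPM (0.665 to 0.922) and Pak1 79.414 CPM (49.1 to 54.0). The total of WT Sham 3 was 26.55 M (38.2 M to 39.3 M) and that of WT MTE 4 26.461 M (38.2 M to 40.05 M). Esr1 in WT MTE 2 was 37.885 CPM (26.97 to 27.6). In KO MTE 1 the extracellular matrix mean was 8.3313 log2 CPM (7.93 to 7.99) and Ppl 2.6933 CPM (1.77 to 1.87).

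The overload response differed between KO and WT by camera in 9 lists, and in 0 with an estimated correlation or by fry. The median log2 difference was 0.30537 for oxidative phosphorylation, 0.4011 for neuromuscular junction, 0.19688 for cytosolic ribosomal proteins, 0.32837 for fast fibre, 0.33219 for glycolysis and 1.6624 for macrophage genes. It was -0.36736 for heat shock, -0.16186 for numbered Zfp and -0.16061 for growth factor genes. Without WT Sham 1 and KO Sham column 3 the macrophage difference turned to -0.547 and that of numbered Zfp genes to 0.0783, both called by camera, and the calls of junction, ribosomal and growth factor genes were lost.

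Whether chance could group the libraries so was examined by refitting other splits of the same libraries. For WT MTE against WT Sham 1 of 35 splits, the real one, called as many as 4355 genes. The highest other, with WT Sham 1 grouped with WT MTE 1 to 3, called 3354. KO MTE against WT MTE gave 253 genes in the real split and at most 0 in the others (1 of 35). KO MTE against KO Sham gave 4454 and at most 310 (1 of 35). In these 3 comparisons a chance split is argued against, at the smallest share that 35 splits allow. Splits cannot separate surgery or genotype from anything else that differed between the same libraries. For KO Sham against WT Sham, 3 of 35 splits called at least the real 88 genes, so chance was not excluded. The highest other called 252, with WT Sham 1, WT Sham 4 and KO Sham column 1 set against the rest. Another called 191, with WT Sham 1 and KO Sham columns 1 and 2. What sets these libraries apart was not tested. For the interaction, 100 of 100 drawn splits called at least the real 0 genes, with 19 as the highest. With a real count of 0 this outcome was certain in advance, so these splits do not bear on chance.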

How the results depend on the processing

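The tests chosen only after the data were seen were sample quality weights, 1 surrogate variable and leaving out both libraries that stood apart. Of 321 named gene results past the threshold, 0 reversed under any alternative run. RLE size factors kept 314, DESeq2 318 of 319, limma voom 312, no filter 321, the stricter filter 312 of 312, the compared groups alone 289, quality weights 317, 1 surrogate variable 309, both libraries left out 305, and 225 were kept without each single library in turn. The cause of the changes was not tested unless stated. Depth limits the genes with few counts, and genes changed 1.5-fold were rarely recovered in simulated data.

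With DESeq2 KO Sham against WT Sham gave 152 higher and 126 lower, which kept the 57 and 31, KO MTE against WT MTE 500 and 154, which kept the 209 and 44, the interaction 10 higher, and Trim28 in KO MTE passed the threshold (-0.97181), as with limma voom (-0.99465). With the compared groups alone, KO Sham gave 4 and 2, Trim28 in KO Sham lost its call (-1.8611), KO MTE gave 395 and 180, and Trim28 in KO MTE passed (-0.94314). At a fold of at least 2, WT overload gave 1485 and 579, KO MTE 120 higher and KO overload 677 lower, by construction.

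With quality weights WT overload gave 4832 and 3629, KO Sham 176 and 191, KO MTE 790 and 593 and KO overload 3517 higher, and Trim28 passed in WT overload (0.60447) and KO MTE (-0.99588). With 1 surrogate variable KO Sham gave 173 and 144, KO MTE 615 and 220, and Trim28 in KO MTE passed (-0.97161). Without WT Sham 1 and KO Sham column 3, WT overload gave 4164 and 3492, KO Sham 102 and 134, KO MTE 553 and 280 and the interaction 1 lower. Trim28 then passed in WT overload (0.59463) and KO MTE (-0.97377), 5 lists were called in KO Sham and 14 in the interaction, and the correlation of the KO Sham and WT overload effects was 0.35126. Lists called by camera both with and without these libraries whose median reversed were interferon (0.3167) and extracellular matrix (0.29764) in KO Sham and numbered Zfp (0.078295) and macrophage genes (-0.54701) in the interaction. Called only without them were, in the interaction, extracellular matrix (-0.77106, from -0.30939), cell cycle (-0.84675, from -0.20786), tendon (-0.44015) and amino acid response (-0.31455) and, with a sign opposite to that with all libraries, mitochondrially encoded (0.58847), interferon (-0.5289), fatty acid oxidation (0.19994) and erythroid genes (-0.77406). In KO Sham these were junction (0.44864) and, with the opposite sign, mitochondrially encoded genes (-0.51575), in KO MTE numbered Zfp (0.035832) and progenitor genes (-0.29119), in KO overload erythroid genes (-1.278) and in WT overload interferon genes (0.9735).

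With an estimated correlation 0 lists were called in each of the 4 comparisons and the interaction, and fry called 0 in KO Sham, 1 in KO MTE and 0 in the interaction.

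With a replicate block on the numbered libraries, the genes higher in WT MTE vs WT Sham were 3005 and the genes lower in WT MTE vs WT Sham 2481, against 2619 and 2178 without the block on those libraries. The genes higher in KO MTE vs WT MTE were 288 and the genes lower in KO MTE vs WT MTE 76, against 237 and 55. Trim28 passed in WT overload (0.45691) and KO MTE (-0.98505), and 20 and 13 lists were called. The numbers were not taken to pair the samples, because the labels give them only as part of a sample title. Deviations of same-numbered libraries correlated at 0.31, 0.17, -0.0080 and 0.17 for WT Sham with WT MTE. The values were 0.46, 0.18, 0.065 and 0.22 for WT MTE with KO MTE and 0.29, -0.11, 0.18 and 0.040 for WT Sham with KO MTE. The best match in WT MTE had the same number for WT Sham 1, 2 and 4. In KO MTE it did for WT MTE 1, 2 and 3 and for WT Sham 1 and 3. A link between same-numbered libraries is therefore not excluded. No paired analysis was possible because the numbers of the KO Sham columns may have been reassigned (3 columns for 4 labelled samples), for KO Sham against WT Sham, KO MTE against KO Sham, the interaction and the correlations.

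Leaving out each library in turn gave 1742 to 3674 higher and 1246 to 3021 lower in WT overload, with Trim28 at 0.33 to 0.59. KO Sham gave 27 to 51 higher and 9 to 52 lower, with Trim28 at -2.06 to -1.56, and KO MTE 82 to 231 higher and 6 to 38 lower, with Trim28 at -1.12 to -0.87. KO overload gave 1278 to 2503 higher and 953 to 2623 lower, with Trim28 at 1.01 to 1.52, and the interaction 0 to 1 higher and 0 to 0 lower, with Trim28 at 0.56 to 1.07. Lists called ran from 18 to 21 in WT overload, 5 to 18 in KO Sham, 10 to 15 in KO MTE, 13 to 19 in KO overload and 8 to 12 in the interaction. The correlation of the overload responses ran from 0.72 to 0.83, that of the knockout effects from 0.23 to 0.47, and that of the KO Sham and WT overload effects from -0.058 to 0.23.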

Other observations

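None of the values here comes from a planned test; all were chosen after they were seen. Genes that resemble pericentromeric repeats differed widely between libraries. Gm10800 lay at 13346 CPM in KO Sham column 3, 5981 CPM in WT Sham 3, 5459 CPM in WT MTE 4 and 1488 CPM in WT Sham 4, and at 2.20 to 755 CPM in the other libraries. The libraries with the highest values were those with the lowest total counts, 21.1 M, 26.6 M and 26.5 M. Gm10801, Gm21738, Gm10718 and Gm10719 were highest in the same libraries. Counts of these genes and of Gm10800 were whole in 0 or 1 libraries, so their values are uncertain.

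In WT Sham 1, several inducible genes of innate immunity stood apart from the mean of the other WT Sham libraries. Saa3, an acute phase gene, was 709 CPM against 0.976, Iigp1, an interferon-inducible GTPase, 1809 against 34.4, Igtp, another of that family, 881 against 17.2, the chemokine gene Cxcl9 86.7 against 1.10, and Adgre1, which encodes the macrophage antigen F4/80, 354 against 12.7. In KO Sham column 3, Col1a1, a chain of the main fibrillar collagen, was 38.04 CPM.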
